A study of Mus musculus with 18 samples.

How the data were processed

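RNA of mouse embryos was extracted, primed with oligo(dT) and amplified, which places most reads near the 3′ ends of polyadenylated transcripts, per the labels' protocols. The 18 libraries fall into 6 groups of 3, wild type or Oct4 null embryos at E2.5, E3.75 and E4.5. The series text gives 3 embryos per genotype and stage and says nothing more about how libraries were made, so p-values measure the spread between these libraries.

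The authors deposited 1 table per stage in CPM, read counts scaled to a library total, and the submitters' processing notes name edgeR and the mm9 genome build. The aligner, the counting tool and the annotation are not given in the sources used here. Each column sums to 1000000 over the genes of its own table, so the tables were scaled separately, and levels of different stages are not on exactly the same scale. Genes low in most libraries had been removed before deposit, since each gene reaches about 10.3 CPM or more in 3 of the 6 libraries of its table. The header names all 3 wild type columns of E4.5 alike, so these libraries have no replicate number and are called A, B and C in column order. Of the genes, 6968 of 7082, 6546 of 6648 and 6443 of 6545 had a symbol in the reference gene table, matched by identifier. Coordinates are not given, because the tables hold none.

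CPM values were whole multiples of the worth of 1 read, and dividing by it gave whole reads for 121650 of 121650 values (100%, within 0.01 reads). The totals so recovered give the depth. In the shallowest library 1 read was worth 2.74 CPM and in the deepest 0.5202 CPM. Intervals cover spread between libraries, not counting error in the amplified RNA, and these reads carry no stated molecular identifiers.

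Because the files hold CPM and not counts, limma took the place of the edgeR test on which the design had first settled, as the design foresaw. limma 3.58.1 (R 4.3.3) was fitted to log2(CPM + 1) with a trend in the variance and moderated statistics, two-sided, with Benjamini-Hochberg adjustment over the genes of a stage and a threshold of 0.05. A fold change on this scale understates the change of low genes. No further filter on low values was applied. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. DESeq2 left the adjusted p undefined for 1648 of 7082 genes at E2.5, 2320 of 6648 at E3.75 and 3934 of 6545 at E4.5, so its counts cover fewer genes than those of limma.

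Differences of the genotype effect between stages were fitted in limma over all 18 libraries as group means. The design had excluded them if tables were scaled separately. They were run all the same, a choice made after seeing the data, because a scale shared by a table cancels within a stage. Comparisons between stages of wild type embryos were not run for that reason. Of 18 gene lists fixed before the data were examined (epiblast and pluripotency, primitive endoderm, trophectoderm, FGF and MAPK targets, glycolysis, TCA cycle, oxidative phosphorylation, sterol and fatty acid synthesis, one-carbon and amino acid metabolism, p53 targets and apoptosis, cell cycle, DNA methylation and chromatin, oocyte and maternal, 2-cell stage, maternal somatic cells, immediate early and heat shock, mitochondrially encoded, and Y-linked genes with Xist), those with at least 4 measured members were tested with camera, with a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a stage. The design also named fry, which asks whether a list changed without comparing it with other genes. It was run with all libraries of a stage only. These tests ran on log2(CPM + 1), where the design had named log-CPM with TMM factors. The FGF and lineage lists share members, and none was chosen on these samples.

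Genes are named by a rule fixed before the data were examined. It takes Pou5f1, then the 10 greatest changes per direction among genes that passed, had a mean of at least 10 CPM and whose null libraries all lay on one side of the wild type libraries, then 8 lineage genes, then up to 4 passing members of each list by smallest p, or 2 with the smallest p where none passed. For differences between stages it takes the 5 greatest per direction. Of the lineage genes, Sox2 was not analysed here, nor were Gata4, Sox17 and Pdgfra at E2.5 and Sox17 at E4.5.

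The distance of each library from the best weighted mix of the other two of its group was computed on the recovered reads of genes with at least 5 reads in each, with and without thinning to equal depth. Alternatives were leaving out each library, the first 2 libraries of each group, TMM and DESeq2 size factors, pseudocounts of 0.1 and 5, a mean CPM minimum of 10, a replicate block at E2.5 and E3.75, a fit over all 18 libraries, thinned reads, and the edgeR and DESeq2 tests.

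The tests were checked on simulated reads for the real genes and library sizes, with 200 genes changed. For null against wild type at E2.5 (7082 genes) limma found 88.1% of genes changed 4-fold, 55.7% of those changed 2-fold and 23.8% of those changed 1.5-fold, with 5.04% false calls when the 3 libraries of a group were independent. At E3.75 (6648 genes) the shares were 98.6%, 79.1% and 35% with 3.95% false calls, and at E4.5 (6545 genes) 93.9%, 49.2% and 11% with 3.85%. For the difference between E3.75 and E2.5 (5430 genes) they were 94.9%, 41.3% and 5.08% with 1.9% false calls. With the third library drawn as an equal mix of the other two, false calls were 68.4%, 63.7% and 64.8% at the 3 stages, and with the first 2 libraries alone they were 4.67%, 1.77% and 4.88%. A simulated rise of the oxidative phosphorylation list was found by camera at each stage, with 0 other lists called. Simulated genes varied independently, so this does not check list calls among correlated genes. In the real libraries of E4.5 the estimated correlation was 0.362 for the oxidative phosphorylation list and 0.675 for the mitochondrially encoded list.

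Spearman correlations between libraries of a group were 0.882 to 0.976 at E2.5, 0.93 to 0.97 at E3.75 and 0.901 to 0.97 at E4.5, and between groups of a stage 0.897 to 0.955, 0.903 to 0.956 and 0.886 to 0.948. No 2 libraries of a group were duplicates, since their counts differed by 1.42 to 6.29 times sampling variance.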

Results

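The series measured polyadenylated RNA in mouse embryos of the CD1 strain that were wild type or null for Oct4 (gene Pou5f1), a transcription factor of pluripotent cells. Embryos came from 3 stages, E2.5 (before the blastocyst), E3.75 (blastocyst) and E4.5 (late blastocyst), with 3 libraries per genotype at each stage, so 18 libraries in 6 groups. The series title gives the question as which genes depend on Oct4 in the embryo. Levels were deposited as CPM, read counts scaled to a library total of 1000000, in 1 table per stage holding 7082 genes at E2.5, 6648 at E3.75 and 6545 at E4.5. The reads behind the values ranged from 364936 in Oct4 null library 1 of E4.5 to 1922432 in Oct4 null library 2 of E2.5. Median depth was higher in null than in wild type libraries at each stage, at 1917754 against 916720 reads at E2.5, 1375610 against 576078 at E3.75 and 1314657 against 543033 at E4.5. Fold changes below are log2(CPM + 1) differences, null minus wild type, with the standard error (SE) and adjusted p of limma.

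The third library of each group lay close to a weighted mix of the other two. At equal depth its variance around the best mix was 1.05 to 1.24 times sampling variance in the 6 groups, against 1.31 to 2.9 times for the first and second libraries. The labels give 3 embryos per genotype and stage, and means, SDs and tests below use n = 3. If the third libraries are not independent of the others, the SEs, intervals and p-values from all libraries can be too small. A fit without a first or second library keeps the third, so its p-values can be too small and its count of genes too high. In simulated reads with 200 genes changed, the third library was drawn as an equal mix of the other 2 with sampling noise only. Of limma calls, 68.4% at E2.5, 63.7% at E3.75 and 64.8% at E4.5 were then false. This case is more extreme than the real libraries, whose variance around the best mix was above sampling variance. The real best weights were 0.23 in the null group of E4.5 and 0.41 to 0.57 in the other groups. The simulated case gave 325 false calls at E2.5, 275 at E3.75 and 225 at E4.5. The real libraries gave 42, 545 and 0 calls in all. The simulated numbers of false calls therefore do not carry over to E2.5 and E4.5. At E3.75 the real calls were more than the simulated false calls. A share of false calls as high as simulated is not excluded there. Because of the mix, the number of genes called at each stage is also given for the first 2 libraries of each group. The count in the lists at E3.75 is given in the same way, a comparison chosen after seeing the data.

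**Figure D1:**
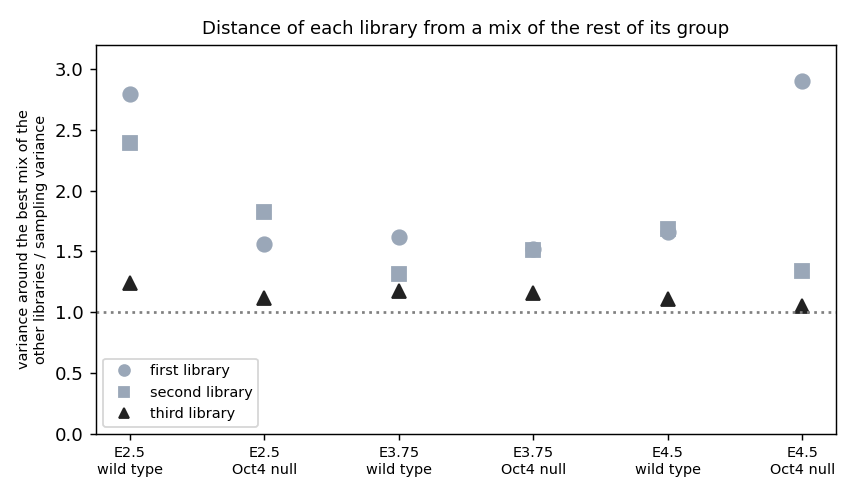
Variance of each library around the best weighted mix of the other libraries of its group, divided by sampling variance, after thinning the reads of a group to equal depth (y axis), for the 6 groups (x axis). Circles mark the first library, squares the second and triangles the third, the dotted line marks sampling variance, and the triangles lie between 1.05 and 1.24.

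Pou5f1 (ENSMUSG00000024406), the targeted gene, was lower in all 9 null libraries than in any wild type library of the same stage. At E2.5 the wild type libraries held 1809, 2093 and 1723 CPM and the null libraries 931.1, 1011 and 963.1 CPM. Means at E3.75 were 509 ± 114.5 CPM (SD, n = 3) in wild type and 257.6 ± 33.32 CPM in null libraries, and at E4.5 they were 230.6 ± 45.9 and 111.5 ± 26.89 CPM. The null to wild type ratio was 0.518 at E2.5 (95% interval 0.457 to 0.588), 0.514 at E3.75 (0.424 to 0.623) and 0.484 at E4.5 (0.358 to 0.652). Pou5f1 passed the limma threshold at E2.5 (adjusted p = 0.00105) and E3.75 (adjusted p = 8.57e-05), and kept it with any 1 library left out and with the first 2 libraries. At E4.5 it did not pass (adjusted p = 0.125). There it passed without Oct4 null library 1 (0.0108), with all 18 libraries in one fit (0.00192), with thinned reads (0.0264), in edgeR's quasi-likelihood test (0.0264), in DESeq2 (0.000121) and in edgeR's exact test (4.46e-05), against 0.832 with the first 2 libraries. Reads came mostly from the 3′ ends of transcripts and the labels do not say which part of the gene was deleted, so a remaining signal does not check the genotype.

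**Figure D2:**
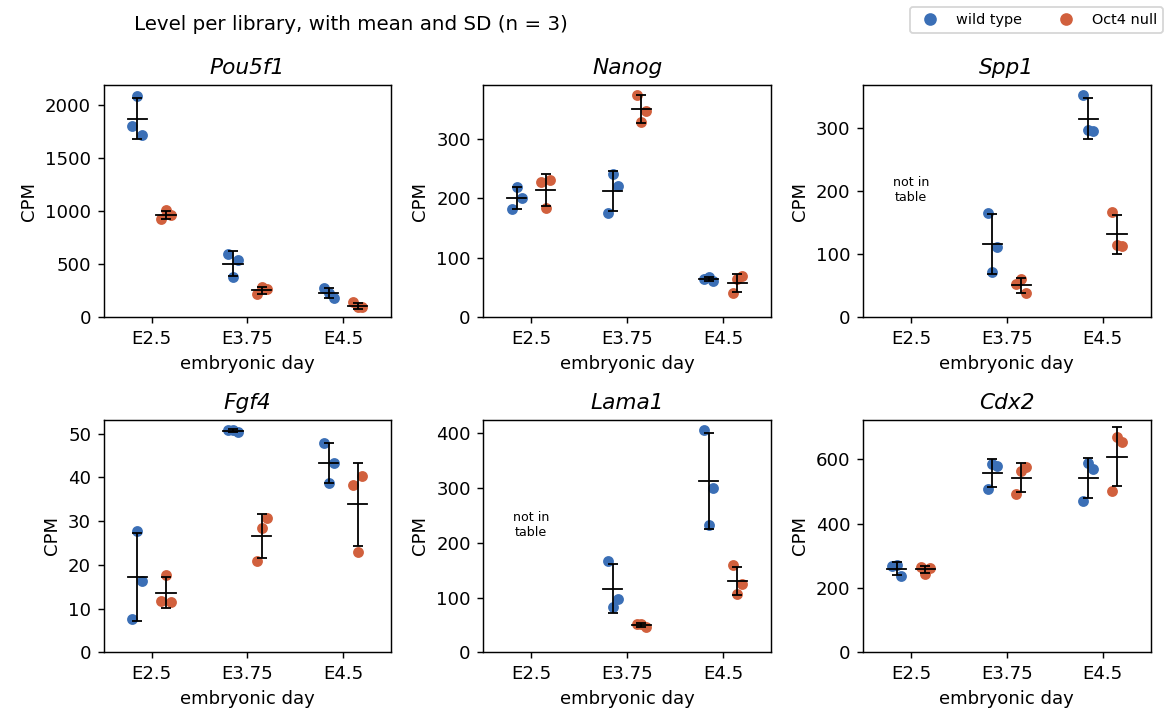
CPM (y axis) of Pou5f1, Nanog, Spp1, Fgf4, Lama1 and Cdx2 at each embryonic day (x axis), where points are libraries and bars the mean with SD (n = 3 per genotype). Pou5f1 null libraries lie below the wild type libraries of their stage, and Nanog null libraries lie above them at E3.75.

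The comparison at E2.5 asks which genes differ between genotypes before the blastocyst forms. Hand1 (ENSMUSG00000037335), a trophoblast transcription factor, rose from 142.8 ± 11.46 CPM in wild type to 278.5 ± 16.93 CPM in null libraries (SD, n = 3; log2 fold change 0.96, SE 0.12, adjusted p = 0.0101, limma). Fbxo15, an F-box protein of pluripotent cells, rose from 432.7 to 802.4 CPM (log2 fold change 0.90, adjusted p = 0.0081). Mfge8, a milk fat globule protein, and Vamp8, a membrane fusion protein, rose by 0.93 and 0.92 log2, and Cited1 rose by 0.61. Scd2, a fatty acid desaturase, fell by 0.69, Cldn6, a tight junction protein, fell by 0.85, Ly6a fell by 0.91 and the histone deacetylase Hdac2 fell by 0.68 on the log2 scale. The greatest rises by the naming rule were those of Arl4a (2.13), Mybpc2 (1.47), Rps18 (1.23), Ovol1 (1.21) and Gpsm1 (1.15), and after Nek6 (-1.13) the greatest falls were those of Rpsa-ps10 (-0.95), a ribosomal protein pseudogene, and Pou5f1. Rps18 and Rpsa-ps10 can share reads with near-identical copies, so their values are uncertain.

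Lineage genes showed few calls at E2.5. Nanog, a pluripotency factor, stood at 200.7 ± 18.36 CPM in wild type and 213.8 ± 26.25 CPM in null libraries (SD, n = 3), Cdx2, a trophectoderm factor, at 259.1 and 257.3 CPM, and Gata6, a primitive endoderm factor, at 177 and 234.7 CPM (log2 fold change 0.41, adjusted p = 0.103, but 0.0298 without wild type library 1 and 0.0327 in edgeR's exact test). Of the trophectoderm list, 1 of 21 measured genes rose (Hand1) and 1 fell (Cldn6), and 8 passed when adjusted over the list alone (6 higher, 2 lower). Of the epiblast and pluripotency list 1 of 20 rose (Fbxo15; adjusted over the list alone, 1 higher and 1 lower), and of the primitive endoderm list 1 of 18 rose (Cited1; adjusted over the list alone, 2 higher and 1 lower). Sterol and fatty acid synthesis had 1 of 19 fall (Scd2; adjusted over the list alone, 1 higher and 2 lower) and DNA methylation and chromatin 1 of 18 (Hdac2; adjusted over the list alone, 1 higher and 3 lower). In the other lists no member passed over all genes, and 0 to 4 members per list passed when adjusted over the list alone. No list of the 17 tested passed camera, with the smallest adjusted p at 0.408, or fry, with the smallest at 0.164.

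Over all 7082 genes, limma called 42 at E2.5, 29 higher and 13 lower in null libraries. All 42 had null libraries that did not overlap the wild type libraries. Such a gap was seen in 27.8% of genes. The 10% that chance gives holds only for exchangeable libraries, which the third libraries may not be, so this share is not read as an excess. edgeR's quasi-likelihood test on the recovered reads called 179 and DESeq2 232, with 1648 genes left without an adjusted p. Of the 22 named genes that passed, Pou5f1 alone passed with every single library left out in turn. The first 2 libraries gave 1 call, Pou5f1, and the count fell to 1 without Oct4 null library 1, 2 or 3 and to 9 without wild type library 3, while it was 390 without wild type library 1 and 773 without wild type library 2. The counts of 390 and 773 come from fits that keep wild type library 3, which lay close to a mix, so they can be too high.

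The comparison at E3.75 addresses the blastocyst, in which epiblast and primitive endoderm separate. Nanog (ENSMUSG00000012396) was higher in null libraries, at 349.2 ± 23.21 CPM against 211.9 ± 33.53 CPM in wild type (SD, n = 3; log2 fold change 0.73, SE 0.12, adjusted p = 0.000566, limma). Other genes of the epiblast list fell. Spp1 (osteopontin) went from 116.2 ± 46.87 to 50.59 ± 11.27 CPM (-1.13, adjusted p = 0.00346), Tdgf1, a Nodal co-receptor, fell by 0.95 (adjusted p = 0.00724), and Fgf4, a growth factor of the inner cell mass, went from 50.68 ± 0.31 to 26.59 ± 5.13 CPM (-0.92, adjusted p = 0.0133). Dppa2 rose by 0.86. In all, 3 of 24 measured genes of the epiblast and pluripotency list rose and 8 fell, and 14 passed when adjusted over the list alone (4 higher, 10 lower).

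Genes of the primitive endoderm list moved both ways at E3.75, with more falls than rises. The laminin genes Lama1 (115.9 ± 45.09 to 49.94 ± 2.98 CPM, SD, n = 3; log2 fold change -1.13, adjusted p = 0.00144, limma) and Lamb1 (198 ± 48.7 to 99.43 ± 18.17 CPM; -0.98, adjusted p = 0.000738) fell, as did the transcription factor Sox17 (37.37 to 15.89 CPM, adjusted p = 0.0132) and the receptor Pdgfra (26.15 to 9.735 CPM, adjusted p = 0.0195). Dab2, an endocytic adaptor, rose from 629.5 ± 42.42 to 986.2 ± 53.24 CPM (0.65, adjusted p = 3.2e-05) and Cited1 rose by 0.68. Gata4 stood at 20.12 ± 10.74 and 8.508 ± 2.705 CPM (adjusted p = 0.121, but 0.0445 without wild type library 2) and Gata6 at 134.7 ± 4.52 and 143.4 ± 11.68 CPM (adjusted p = 0.744). Of 26 measured genes 4 rose and 8 fell, with 16 passing when adjusted over the list alone (4 higher, 12 lower). The list's camera adjusted p was 0.0523, and that of the epiblast list was also 0.0523, each with adjusted p = 0.369 with an estimated correlation. Without Oct4 null library 2 each of these lists passed (0.0218), and the primitive endoderm list also without Oct4 null library 3 (0.0416) and with the first 2 libraries (0.0385). With all libraries both passed with a pseudocount of 5 (0.0448), and the primitive endoderm list also with TMM factors (0.0413) and DESeq2 size factors (0.0426). Tdgf1 lost its call without Oct4 null library 1 (adjusted p = 0.0563). Spp1 did not pass in DESeq2 (adjusted p = 0.0596). Fgf4 did not pass in DESeq2 (0.0603) or with all 18 libraries in one fit (0.12), and lost its call with the first 2 libraries (adjusted p = 0.0815) and without Oct4 null library 1 (0.0765) or wild type library 3 (0.0544), Sox17 without Oct4 null library 1 (0.0807), and Pdgfra without wild type library 1 (0.0706) or Oct4 null library 1 (0.102).

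Trophectoderm genes showed no common direction at E3.75. Of 24 measured, 3 rose (Dab2, which the primitive endoderm list also holds, Ptges and Tead4) and 2 fell, including Tspan8 from 1635 ± 49.34 to 1222 ± 55.3 CPM (SD, n = 3), with 7 passing when adjusted over the list alone (3 higher, 4 lower). Cdx2 was at 557.8 ± 43.45 and 543.2 ± 44.35 CPM. Of the FGF and MAPK target list, 1 of 8 fell (Fgf4) and 3 passed when adjusted over the list alone, while 0 of this list passed over all genes with the first 2 libraries. Camera's adjusted p was 0.526 for the trophectoderm list and 0.262 for the FGF and MAPK list.

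Of the TCA cycle list, 8 of 25 measured genes fell at E3.75 and none rose (14 passed when adjusted over the list alone, 13 of them lower), among them Suclg1 (1109 ± 110.3 to 859.9 ± 30.33 CPM, SD, n = 3), Mdh1 (278.7 to 190 CPM) and Sdhb (518.8 to 395.6 CPM). Of the oxidative phosphorylation list, 11 of 38 fell and none rose (18 adjusted over the list alone), including Atp5c1 (1248 to 1003 CPM), Cox4i1 (3575 to 2993 CPM) and Uqcrc1 (957.2 to 741.2 CPM). Of the glycolysis and glucose uptake list, 1 of 15 fell (Eno1) and 13 of 15 were lower (6 adjusted over the list alone). Camera with a preset correlation gave adjusted p = 0.00401 for each of these 3 lists, and each call was lost with adjusted p = 0.369 with an estimated correlation. Median log2 fold changes were -0.33, -0.22 and -0.42 for the TCA cycle, oxidative phosphorylation and glycolysis lists. With the first 2 libraries 1 gene of the TCA cycle list fell and 0 of the other two lists, and the oxidative phosphorylation list did not pass camera (adjusted p = 0.0584).

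Other lists moved in part at E3.75. Of the cell cycle list, 6 of 25 fell and none rose (7 adjusted over the list alone), including the replication licensing genes Mcm2 (394.9 ± 42.41 to 253.3 ± 26.23 CPM, SD, n = 3; adjusted p = 0.00108, limma) and Mcm6, Ccnd3 and Cdk1, and camera's adjusted p was 0.0523 (0.0168 without Oct4 null library 1, 0.0448 with a pseudocount of 5, and 0.441 with an estimated correlation). Of the one-carbon and amino acid list, 2 of 21 rose and 3 fell (adjusted over the list alone, 3 higher and 3 lower): Psat1, a serine synthesis enzyme, went from 1240 ± 88.13 to 1966 ± 105 CPM and Gldc, of the glycine cleavage system, from 436.7 to 562.6 CPM, while Ahcy and Slc7a3 were among the falls. Sterol and fatty acid synthesis had 3 of 20 fall (Srebf2, Fasn and Scd2; 3 adjusted over the list alone), DNA methylation and chromatin 1 of 15 (Mbd3; 1 adjusted over the list alone), immediate early and heat shock 2 of 10 (Hsph1 and Dnajb1; 2 adjusted over the list alone), p53 targets and apoptosis none of 11 (0 adjusted over the list alone), and the mitochondrially encoded list 1 of 7 (mt-Co1, 7096 to 5388 CPM; adjusted over the list alone, 2 higher and 1 lower). None of these lists passed camera at E3.75 with all libraries and a pseudocount of 1. With the first 2 libraries the calls in these lists were 1 cell cycle fall (Mcm2), 1 one-carbon rise (Psat1), 1 sterol fall (Srebf2) and 1 mitochondrially encoded fall (mt-Co1).

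Among transcripts of other cells and earlier stages, Khdc3 and Tcl1 of the oocyte and maternal list fell at E3.75 (2 of 5 measured; 2 adjusted over the list alone; camera adjusted p = 0.286), with Khdc3 at 2349 ± 130.3 and 1798 ± 72.69 CPM (SD, n = 3). Of 3 measured genes of the 2-cell list, Pramel6 (464.1 to 708.5 CPM) and Sp110 rose (2 adjusted over the list alone). Of 3 measured genes marking maternal blood, oviduct, uterus or cumulus cells, the globin Hba-a1 rose from 24.04 ± 4.29 to 62.83 ± 28.37 CPM (adjusted p = 0.0052, limma; 1 adjusted over the list alone). Of the list of Y-linked genes and Xist, none of 2 measured genes passed over all genes (2 adjusted over the list alone). Xist stood at 40.2 ± 12.32 and 21.08 ± 5.41 CPM (adjusted p = 0.0509, limma), and its antisense partner Tsix, whose reads were not shown to be separable from those of Xist, at 12.12 and 4.407 CPM. With the first 2 libraries the calls in these lists were Khdc3, Pramel6 and Hba-a1.

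The greatest rises at E3.75 by the naming rule were those of Tceal9 (1.77), Rab5a (1.61), Dnah2 (1.58), Stat5a (1.47) and Rufy3 (1.41), all under 30 CPM in both groups, followed by Allc (1.38), Zfand5 (1.30), Agrp (1.30), Sp110 (1.28) and Hba-a1 (1.27). The greatest falls were those of Ppp1r1a (-2.04), the caudal-type factor Cdx1 (-1.99), the ectonucleotidase Nt5e (-1.69), Popdc3 (-1.69), Drosha (-1.54), 2310030G06Rik (-1.52), Etaa1 (-1.41), Ssx2ip (-1.40), Rab25 (-1.39) and Pdgfra (-1.37). All of these falls were in genes with means under 30 CPM in both groups. Their null means ran from 3.527 CPM (Ppp1r1a) to 9.735 CPM (Pdgfra), so they rest on few reads. In Oct4 null library 1 Cdx1 stood at 2.312 CPM, where 1 read was worth 1.156 CPM. Of the 61 named genes that passed at E3.75, 23 also passed with the first 2 libraries, among them Pou5f1, Nanog, Spp1, Tdgf1, Lama1, Lamb1, Sox17, Pdgfra, Dab2, Cited1, Mcm2, Mdh1 and Psat1. With each library left out in turn 19 passed every time, and calls were lost for up to 33 (without Oct4 null library 1) and 32 (without wild type library 3).

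Over all 6648 genes at E3.75 limma called 545, 239 higher and 306 lower in null libraries, while edgeR's quasi-likelihood test called 552 and DESeq2 288, with 2320 genes left without an adjusted p. Null libraries did not overlap wild type libraries for 533 of the 545 and for 27.2% of all genes. Chance gives 10% only if all libraries are exchangeable, so this share is not read as an excess either. With TMM factors the split was 287 higher and 216 lower. The first 2 libraries called 155, of which 151 were among the 545. They included 1 rise and 2 falls in the epiblast and pluripotency list, 3 and 5 in the primitive endoderm list and 2 and 1 in the trophectoderm list. The count over all genes was 209 without wild type library 3, 221 without Oct4 null library 1 and 287 without Oct4 null library 3.

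**Figure D3:**
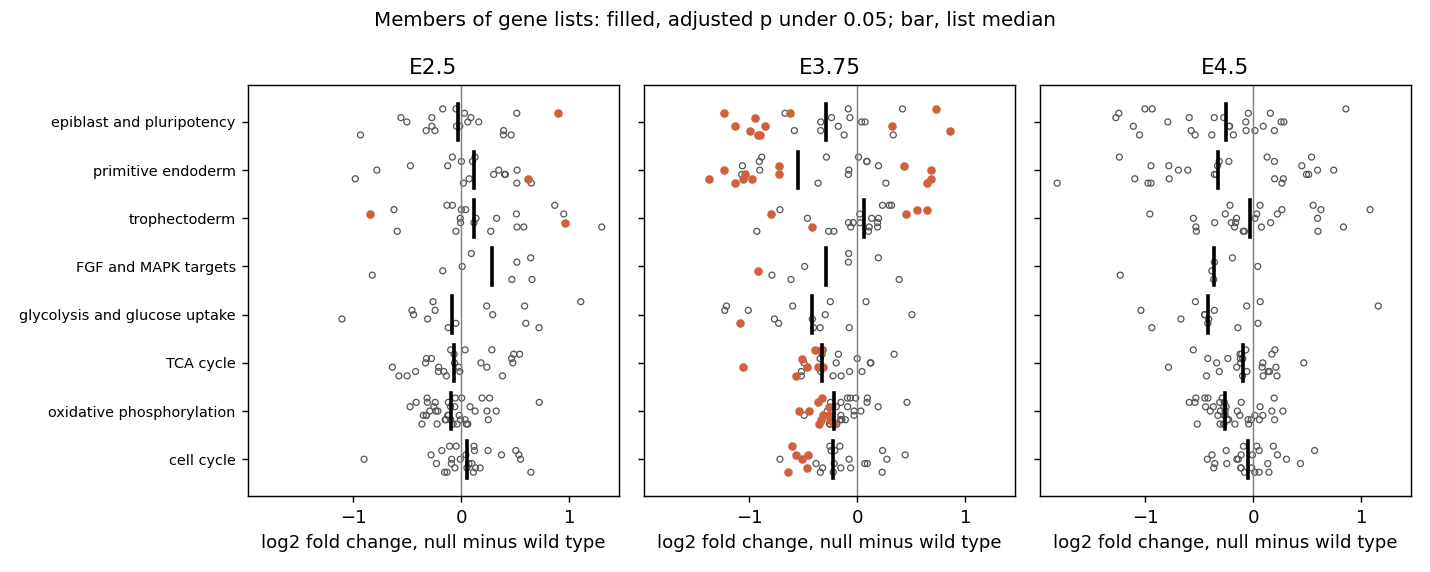
Log2 fold change, null minus wild type (x axis), of the measured members of 8 gene lists (y axis) at each stage, where filled points have an adjusted p under 0.05 in limma and the black bar is the list median. At E3.75 the medians of the TCA cycle and oxidative phosphorylation lists were -0.33 and -0.22.

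At E4.5, when the blastocyst approaches implantation, no gene passed limma's threshold. The smallest adjusted p was that of Spp1 (0.0611), at 314.1 ± 32.58 CPM in wild type and 131.2 ± 31.12 CPM in null libraries (SD, n = 3; log2 fold change -1.27, SE 0.17). Spp1 passed with TMM factors (adjusted p = 0.0494), a pseudocount of 5 (0.0448) and thinned reads (0.00143), without Oct4 null library 1 (0.00058), in edgeR's quasi-likelihood test (0.00521), in DESeq2 (1.24e-08) and in edgeR's exact test (2.48e-11), while with the first 2 libraries its adjusted p was 0.832. Tdgf1 passed without Oct4 null library 1 (0.0389), in edgeR's quasi-likelihood test (0.0264), in DESeq2 (0.0101) and in edgeR's exact test (8.11e-05), against 0.832 with the first 2 libraries, and Gata4 in the exact test (0.0103). Tdgf1 stood at 87.52 ± 9.23 and 43.03 ± 2.74 CPM, Lama1 at 313.4 ± 87.86 and 130.4 ± 26.25 CPM, Lamb1 at 226 ± 50 and 112.9 ± 9.95 CPM, and Gata4 at 37.93 ± 7.52 and 18.94 ± 0.29 CPM. Nanog stood at 64.63 ± 3.15 and 58.08 ± 14.94 CPM and Cdx2 at 541.9 ± 63.37 and 607.7 ± 92.26 CPM. Hand1 stood at 42.96 ± 17.8 and 87.1 ± 4.01 CPM, Fgf4 at 43.28 ± 4.55 and 33.8 ± 9.55 CPM, Pdgfra at 15.02 and 7.357 CPM, and Gata6 at 62 and 53.82 CPM.

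Gene lists were shifted at E4.5 in camera with a preset correlation, 8 of the 14 tested and all toward lower levels in null libraries. These were epiblast and pluripotency (19 of 26 members lower, adjusted p = 0.000241), primitive endoderm (15 of 26 lower, adjusted p = 0.0211), FGF and MAPK targets (5 of 6 lower, adjusted p = 0.0105), glycolysis and glucose uptake (11 of 14 lower, adjusted p = 0.000765), oxidative phosphorylation (31 of 39 lower, adjusted p = 4.03e-05), one-carbon and amino acid metabolism (16 of 21 lower, adjusted p = 0.0105), DNA methylation and chromatin (11 of 15 lower, adjusted p = 0.00374) and mitochondrially encoded transcripts (6 of 7 lower, adjusted p = 0.0289). Every one of these calls was lost with an estimated correlation, the adjusted p then ranging from 0.137 for the epiblast list to 0.389 for the mitochondrially encoded list. Members with small p in those lists included Ldha (101.9 to 48.19 CPM), Cox6b1 (1217 to 806.9 CPM) and Asns (273.8 to 174 CPM), none past the threshold over all genes. Passing when adjusted over the list alone, all lower in null libraries, were 4 epiblast, 3 glycolysis, 6 oxidative phosphorylation, 4 one-carbon, 4 mitochondrially encoded, 1 oocyte and maternal and 1 FGF and MAPK genes. So did 8 primitive endoderm genes (2 higher, 6 lower), 5 trophectoderm genes (3 higher, 2 lower), 4 TCA cycle genes (1 higher, 3 lower), and 1 gene each of the sterol and 2-cell lists (higher). Camera's adjusted p was 0.0574 for the TCA cycle list, 0.192 for sterol and fatty acid synthesis and for p53 targets, and 0.338 for the cell cycle list. The trophectoderm list had 13 members higher and 13 lower, with a camera adjusted p of 0.582. Without Oct4 null library 1 the primitive endoderm list did not pass (adjusted p = 0.0569) and the TCA cycle list did (0.0317), as it did with TMM factors (0.0345) and DESeq2 size factors (0.034). The mitochondrially encoded list did not pass without wild type library A (0.11) or C (0.0539), without Oct4 null library 2 (0.18) or 3 (0.0903), or with the first 2 libraries (0.134). With thinned reads neither that list (0.0576) nor the one-carbon list (0.0762) passed.

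Against the 0 genes limma called at E4.5, 985 of 6545 had an unadjusted p under 0.05, edgeR's quasi-likelihood test called 42, DESeq2 112 (with 3934 genes left without an adjusted p) and edgeR's exact test 292, and limma with all 18 libraries in one fit called 221 of 5430 genes. Without Oct4 null library 1, the library with the fewest reads, limma called 120 genes, 35 higher and 85 lower, and with any other single library left out or with the first 2 libraries it called 0. Reads of the globin Hba-a1 in that library stood at 145.2 CPM, against 24.34 and 41.7 CPM in the other 2 null libraries and 23.94, 34.9 and 27.57 CPM in wild type. Oct4 null libraries 2 and 3, which remain without library 1, differed by 1.47 times sampling variance. Their pairs with library 1 differed by 4.13 and 2.8 times, so the count of 120 can be too high.

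Differences of the genotype effect between stages were tested on the 5430 genes in all 3 tables. Between E2.5 and E3.75 the effect differed for 61 genes, being higher at E3.75 for 26 and lower for 35. Id3, an inhibitor of bHLH factors, had effects of 1.19 at E2.5 and -0.91 at E3.75 (difference -2.10, SE 0.34, adjusted p = 0.00247, limma), Hand1 of 0.96 and -0.72 (adjusted p = 0.0394) and Dab2 of 0.00 and 0.65 (adjusted p = 0.0317). Between E3.75 and E4.5 it differed for 5 genes, higher at E4.5 for Dctn2 and Tubb5 and lower for Arf2, Rbm8a and Tdrp (1 higher and 9 lower with TMM factors), and between E2.5 and E4.5 for 55, of which 32 had a higher effect at E4.5, or 16 of 55 with TMM factors. The Nanog effects at E3.75 and E4.5 differed by -0.91 (SE 0.23), which did not pass (adjusted p = 0.0933), and those of Pou5f1 differed by -0.09. With the first 2 libraries 0 genes passed in each of these 3 tests, where edgeR's quasi-likelihood test on all libraries called 115, 9 and 124 and DESeq2 130, 70 and 151. With 1 library left out the first count was between 5 and 28, except without wild type library 2 of E3.75 (89) or of E2.5 (131). The second was between 0 and 5, except without wild type library 2 of E3.75 (15) or B of E4.5 (34). The last was between 4 and 28, except without wild type library 1 of E2.5 (55), Oct4 null library 1 of E4.5 (99), wild type library 2 of E2.5 (153) or B of E4.5 (169).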

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

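Differences of the genotype effect between stages, chosen for testing after seeing the data, picked out named genes whose null minus wild type effects differed (limma, adjusted p under 0.05). With the first 2 libraries of each group 0 genes passed, and nothing is offered in explanation. Genotype was also regrouped within both stages. A low share of regroupings with as many genes cannot exclude chance here, although that was the limit set in advance. Regrouping treats the third libraries as exchangeable, which favours the real grouping. It also breaks up an effect common to both stages, which can act either way. Regroupings that kept the genotype split at the earlier stage alone reached 449 genes between E3.75 and E4.5, against the real 5. From E2.5 to E4.5 they reached 361, against the real 55. From E2.5 to E3.75 the highest that kept it at either stage alone gave 20, against the real 61.

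From E2.5 to E3.75 the effect moved by -2.10 log2 for Id3, -2.09 for Cd82, -1.98 for Dusp1, -1.96 for Ndufaf1, -1.83 for Slc44a2, -1.68 for Hand1, -1.47 for Mfge8, -1.10 for Vamp8, -0.94 for Cdk1, -0.88 for Hsph1 and -0.86 for Sdha. It moved by 2.12 for Elobl, 1.97 for Fam122b, 1.72 for Gmpr2, 1.52 for Ppcdc, 1.51 for Xrcc1, 1.10 for Ly6a and 0.65 for Dab2. Of 100 regroupings, 1 (the real one) gave as many as the 61 genes found, and the highest of the others gave 20.

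Between E3.75 and E4.5 the effect moved by -2.25 for Arf2, -1.07 for Rbm8a, -0.55 for Tdrp, 1.07 for Dctn2 and 0.67 for Tubb5. Here 7 of 100 regroupings gave at least the 5 genes found, so chance is not excluded. The highest of the others gave 449 and kept the genotype split at E3.75. The 79 that kept the genotype split at no stage gave at most 5.

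From E2.5 to E4.5 the effect moved by -1.95 for Pank2, -1.88 for Slc44a2, -1.84 for Glipr1, -1.54 for Pfkl, -1.52 for Trp53i11, -1.31 for Rps18 and -1.01 for Vamp8. It moved by 2.05 for Sel1l, 1.93 for BC049730, 1.57 for Srebf2, 1.495 for Ppcdc, 1.34 for Slc43a3, 1.28 for Ly6a, 0.87 for Scd2, 0.70 for Lap3 and 0.68 for Cstb. In this test 4 of 100 regroupings gave at least the 55 genes found, the real one and 3 of the 20 that kept the genotype split at 1 stage. The highest of the others gave 361 and kept the genotype split at E2.5. The 79 that kept it at no stage gave at most 12.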

How the results depend on the processing

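The first 2 libraries, TMM factors, edgeR's quasi-likelihood test and thinned reads were chosen after seeing the data. Unless said otherwise the cause was not tested. At E2.5 the 42 genes became 93 with DESeq2 size factors, 99 with TMM factors, 179 in edgeR's quasi-likelihood test, 232 in DESeq2, 582 in edgeR's exact test, 139 with all 18 libraries in one fit (fewer genes, more samples), 74 with reads thinned to the smallest library and 1 with the first 2 libraries of each group (fewer samples). They ranged from 1 to 773 with 1 library left out. At E3.75 the 545 became 288 in DESeq2, 213 with all 18 libraries, 155 with the first 2 libraries and 363 with thinned reads, and ranged from 209 to 652 with 1 library left out. At E4.5 the 0 became 2 with TMM factors, 1 with a pseudocount of 5, 42 in edgeR's quasi-likelihood test, 112 in DESeq2, 292 in edgeR's exact test, 221 with all 18 libraries and 13 with thinned reads, and ranged from 0 to 120 with 1 library left out.

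Of the lists, 3 were shifted in camera at E3.75 and 8 at E4.5, and 0 at each with an estimated correlation. At E3.75 the count was 6 with a pseudocount of 5 and 3 to 5 with 1 library left out. The primitive endoderm list at E3.75 passed with TMM factors (adjusted p = 0.0413, camera) and with the first 2 libraries (0.0385), over a range of 0.0218 to 0.369. In fry the sterol (adjusted p = 0.00271), oxidative phosphorylation (0.0111), glycolysis (0.0276) and TCA cycle (0.0294) lists passed at E3.75. So did the epiblast and primitive endoderm lists (0.0367 each) and the cell cycle, DNA methylation, and oocyte and maternal lists (0.0377 each). At E4.5 the epiblast list alone passed fry (0.0106).

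The effect differed between E2.5 and E3.75 for 130 genes in DESeq2, 115 in edgeR's quasi-likelihood test, 0 with the first 2 libraries and 5 to 131 with 1 library left out. Between E3.75 and E4.5 the counts were 10 with TMM factors, 70, 9, 0 and 0 to 34 in the same order, and between E2.5 and E4.5 they were 151, 124, 0 and 4 to 169.

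With the replicate block limma called 30 genes at E2.5, 438 at E3.75 and 16 with an effect differing between them. Deviations of each gene from its group mean gave little sign that the numbers pair the libraries. Weak correlations over 3 libraries per group cannot exclude pairing. Between same-numbered wild type and null libraries these deviations correlated at 0.037, 0.12 and -0.003 at E2.5. At E3.75 they correlated at -0.0069, -0.031 and 0.01, and 1 of 6 matched its own number best. No block could be fitted at E4.5, where the wild type columns carry no number. Not run were the wild type comparisons between stages, and no filter was the main setting itself. No named gene or list changed direction with a call in these alternatives. The lowest depth limits low genes, since 1 read was worth 2.74 CPM in Oct4 null library 1 of E4.5.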

Other observations

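The overlap of calls, the tests on the third library, those on Pou5f1 other than the one of wild type RNA, and the one on Oct4 null library 1 of E4.5 were chosen after the result was seen. Genes called at E2.5 and E3.75, in separate libraries, overlapped. Of 5893 genes in both tables, 12 were called as higher at both stages (0.984 expected for independent lists, Fisher's exact test p = 3.46e-11), namely (named after their values were seen) Acot11, Alppl2, Cited1, Cyp2s1, Fam151a, Flvcr2, Gm5612, Pttg1ip, Rps18, Slc6a8, Trim43b and Trim43c, and 7 as lower (0.558 expected, Fisher's exact test p = 3.41e-07), namely Arpc5, Cldn6, Cstb, Lap3, Pou5f1, Prdx1 and Scd2. Genes are not independent, so these p-values are too small. The overlap rests on the 42 calls of E2.5, which came down to Pou5f1 alone with the first 2 libraries and without Oct4 null library 1, 2 or 3, so at most 1 gene would then be shared. Of the genes that rose at E3.75, 186 of 226 measured at E4.5 were also higher there in null libraries (82.3%, against 55.2% of all genes in both tables), and of those that fell, 188 of 283 were also lower (66.4%, against 44.8%).

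At E2.5, reads of the Y-linked gene Eif2s3y averaged 16.29 ± 2.91 CPM in wild type and 14.91 ± 6.56 CPM in null libraries (SD, n = 3), and Xist at E4.5 averaged 14.27 and 23.49 CPM.

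The third library of each group lay nearest to a mix of the other two in 6 of 6 groups at equal depth, which argues against 3 equally independent libraries per group. A technical axis shared by the genotypes of a stage is argued against too, since the difference between the first 2 libraries in wild type correlated with that in null libraries across genes at no more than 0.12 in size. A library made from the material of the other two may account for the pattern and stays open: the variance around the mix was at most 1.24 times sampling variance at equal depth, above what sampling alone gives. No biological explanation was tested.

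Pou5f1 reads stood at about the same share of wild type in null libraries at each stage. A single wild type library labelled null is argued against, since 9 of 9 null libraries lay below every wild type library of their stage. Maternal transcripts stay open: the lower bound of the ratio at E4.5 was 0.358, above the limit of 0.13 set for transcripts decaying since E2.5, but that limit needs a steady wild type level, which went from 1875 to 230.6 CPM as null libraries went from 968.3 to 111.5 CPM. Wild type RNA at a similar share of each null library stays open. Of the 305 other genes called lower at E3.75, 0.984% had an interval wholly below the Pou5f1 fold change of -0.961, though 69 had a lower estimate. Intervals were wide, as that of Nt5e reached -0.90 with an estimate of -1.69. A low share was therefore likely in any case and decides little. A transcript of the deleted allele that keeps its 3′ end stays open and was not tested.

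The count of 0 genes at E4.5 beside 545 at E3.75 was tested in 2 ways. Lower depth is argued against, since libraries of E3.75 thinned to the depths of E4.5 still gave 368 calls. One library apart from the rest may account for it but stays open, since 120 genes passed without Oct4 null library 1 and 0 without any other. Oct4 null library 3, which remains, lay close to a mix in which library 1 had a weight of 0.23. Its closeness to library 2 can raise the count by itself, so leaving library 1 out cannot decide this. A smaller effect of genotype at E4.5 stays open. The effect differed between E3.75 and E4.5 for 5 of 5430 genes (775 at an unadjusted p under 0.05, limma), and effects at these stages correlated at 0.19 across genes. A low count decides little, since the simulated test between E2.5 and E3.75 found 41.3% of 2-fold and 5.08% of 1.5-fold differences. In the separate fits of each stage the median residual SD was 0.282 at E3.75 and 0.319 at E4.5. With all 18 libraries in one fit, which shares its estimate of the spread over stages, the counts were 213 at E3.75 and 221 at E4.5. The contrast of 0 with 545 genes therefore depends on the fit.

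The 6 libraries of a stage allow 10 splits, too few for a share under 0.05. The real split gave 42 genes at E2.5 and 545 at E3.75, where the highest other gave 0 at each stage, and at E4.5 all 10 splits gave 0. Every other split puts both genotypes into each group and parts libraries close to a mix from libraries they resemble. This can raise the spread within groups and favours the real split. The counts of 0 in the other splits were therefore likely in any case and decide little.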
